A study of Mus musculus with 12 samples.

How the data were processed

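Messenger RNA levels were measured by RNA sequencing in 12 mouse samples, in 4 groups of 3: fresh wild type, fresh Otub1 knockout, stimulated wild type and stimulated Otub1 knockout. Groups were taken from the source labels of the samples, which read untreated for the groups called fresh here. Replicates were numbered within a group only to name them. The mice were 6 to 8 weeks old, on the C57BL/6 background, and carried the OT-I T cell receptor, a transgenic receptor for an ovalbumin peptide. Deletion used CD4-Cre, a recombinase that acts in developing T cells. Stimulation lasted 24 h with plate-bound anti-CD3 and with anti-CD28, at 1 µg/ml each. Untreated cells were taken as not cultured, so stimulation and culture form 1 factor. One text of the labels describes all samples as fresh splenic cells, and a cell type tag names dendritic cells, against a design text that names naive splenic CD8 T cells. The labels give no batch and do not say whether replicates came from separate animals, so p-values measure the spread between these samples. In 3 of the 4 groups 1 library had Y-linked reads and the others did not, so these groups hold more than 1 animal. In stimulated wild type the spread may be technical.

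The authors deposited 1 table of raw read counts per gene for each sample, whole numbers with no normalization. Per the submitters' processing notes, TopHat, TopHat2, HTSeq, DESeq2 and the mm10 build were used. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore be shared or lost: Eno1, a main glycolytic enzyme with many pseudogene copies, lay below the filter on low counts. Each file ended with 5 HTSeq summary lines, which were left out of library sizes and tests. They held 5.22% to 6.43% of the total counted in a file, of which entries that were not unique made up the most (2.95% to 3.92% of that total). Ambiguous reads made up 2.02% to 2.17% and reads outside genes 0.169% to 0.526%.

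Library sizes ranged from 15064488 to 25920035 gene counts, and 23420 genes were listed. Replicates were compared before they were averaged. Counts of every pair of replicates in a group differed by more than sampling noise (chi-square per degree of freedom 4.26 to 18.6, over genes with at least 20 counts in the pair), so no pair was treated as 1 library deposited again. Repeats of 1 sample can also differ by more than this noise, so it does not show that replicates are separate animals.

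Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 12759, and scaled by TMM factors, which ranged from 0.988 to 1.01. One quasi-likelihood model with a coefficient per group was fitted to all 12 libraries, with 8 residual degrees of freedom. Contrasts compared knockout with wild type in fresh and in stimulated cells, stimulated with fresh cells in each genotype, and the genotype effects of both states (the interaction). All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "edgeR adjusted p" stands for this test throughout. Levels are CPM, the count of a gene as a share of its library scaled to 1e6 counts, with TMM scaling, as mean ± SD of 3 libraries, and fold changes are on the log2 scale with the standard error (SE) of the fit. A fold against a group with 0 counts was set against a floor of 3 counts over the group. Floors cover counting error only.

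A total of 27 gene lists were fixed, each tested with camera on voom values (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Fry tests whether the members of a list move, on balance, one way, and does not compare them with other genes. The lists were CD8 T cell identity, naive and quiescence genes, activation and costimulation, effector molecules, memory-phenotype and IL-15-responsive genes, inhibitory receptors, IL-2 and STAT5 targets, NF-kappaB targets, AKT-repressed FOXO targets, glycolysis, respiratory chain, cholesterol synthesis, serine, one-carbon and ATF4 targets, ribosome biogenesis, S phase, mitosis, interferon response, immediate early and heat shock genes, and OTUB1 partners and related deubiquitinases. Markers of dendritic cells, B cells, CD4 T cells, NK cells, myeloid cells, erythroid cells and platelets, and sex-linked genes, made up the others. Some genes stand on more than 1 list. Counts of called members are given over all genes tested and adjusted over the list alone. Lists with 1 measured member were not tested with camera.

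Genes are named by a rule. For each knockout comparison, and for stimulation in wild type, these are Otub1, then the 10 highest and the 10 lowest fold changes among called genes with an average log2 CPM of at least 2 and no overlap between the groups, without predicted genes and receptor segments. Up to 4 members of each list with the smallest p were added. For the interaction, 5 genes in each direction were named without the overlap condition. Any other gene is marked as chosen after its values were seen. Some genes that the rule names are not reported here, and counts of genes include them. The groups, tests, lists, naming rule and the alternatives below were chosen before the data were examined, except where stated. The lists were not blind to earlier work. Those of memory-phenotype and of FOXO genes were chosen because Otub1 was known to concern IL-15 responses and AKT in CD8 T cells. That knowledge may come from a study of these same samples, so results of these lists may not be independent of it.

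Alternatives were DESeq2-type size factors and upper-quartile factors in place of TMM, no filter on low counts, a filter of CPM above 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a test against a 1.5-fold change, and each library left out in turn. Added after seeing the data were sex as a covariate and a fit without the libraries with Y-linked reads. A library was taken as male where its summed Y-linked CPM exceeded its Xist CPM. Gene positions come from the RefSeq annotation of GRCm38, the assembly that mm10 names. Figures were drawn with matplotlib 3.10.9.

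The model was tested on simulated counts, with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold for each comparison but the interaction, which had 134, 134 and 132. For knockout against wild type in fresh cells it recovered 68.7% of 1.5-fold, 86.6% of 2-fold and 97.0% of 4-fold changes, in stimulated cells 68.7%, 77.6% and 87.9%, and for the interaction 57.5%, 70.9% and 89.4%. For stimulation it recovered 68.7%, 88.1% and 97.0% in wild type and 67.2%, 89.6% and 97.0% in knockout. False calls were 5.62%, 4.88%, 5.54%, 2.31% and 4.52% of the calls, in the same order. For stimulation the simulated states were otherwise alike, so scaling was not tested where most genes change. Counts were drawn gene by gene, with no shared difference of sex or animal between libraries, so these rates leave such differences out.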

Results

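RNA sequencing was performed on mouse CD8 T cells with and without Otub1, which encodes a deubiquitinase that binds ubiquitin-conjugating enzymes and cleaves ubiquitin chains. Cells were untreated, called fresh here, or taken after 24 h with anti-CD3 and anti-CD28, antibodies that mimic antigen and costimulation. Each of the 4 groups had 3 libraries. Depth was 17389302 ± 2824560 gene counts in fresh wild type, 20531781 ± 1472565 in fresh knockout, 21628582 ± 2233603 in stimulated wild type and 22920696 ± 3319064 in stimulated knockout (mean ± SD, n = 3). Between 14482 and 15384 genes had a count in a library. The first principal component held 90.4% of the variance and separated stimulated from fresh libraries.

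The libraries carried high levels of T cell transcripts. In fresh wild type, Cd8b1, the beta chain of the CD8 coreceptor, was at 1198 ± 72.8 CPM and Lck, the kinase bound to CD8, at 964 ± 15.3 CPM. Transcripts of antigen-presenting cells were present as well. The 14 dendritic cell markers summed to 1641 ± 168 CPM in fresh wild type and 1419 ± 304 CPM in fresh knockout, and to 116 ± 10.4 and 121 ± 2.89 CPM after stimulation. Among the 12 libraries, 3 had Y-linked reads and little Xist: fresh wild-type replicate 3, fresh knockout replicate 2 and stimulated knockout replicate 3. These had the 3 lowest scores on the second principal component, which held 2.10% of the variance. The scores were −13.7, −20.5 and −24.9 in that order, against −6.25 or higher in the others. The main fit had no term for sex, and sex was not told apart from other differences between animals.

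Otub1 itself (chromosome 19, 7198206 to 7206284, GRCm38) was lower in every knockout library than in every wild-type library of the same state. In fresh cells it was at 62.8 ± 15.4 CPM in wild type and 27.6 ± 1.91 CPM in knockout, 43.9% of the wild-type level (log2 fold change −1.19, SE 0.14, edgeR adjusted p = 0.000559). After stimulation it was at 94.0 ± 7.48 CPM in wild type and 14.8 ± 1.26 CPM in knockout, 15.8% of the wild-type level (log2 fold change −2.66, SE 0.14, edgeR adjusted p = 1.35e-07). Stimulation raised Otub1 in wild type by 0.58 on the log2 scale and lowered it in knockout, with a log2 fold change of −0.89 (edgeR adjusted p = 0.000772 and 3.65e-05). Counts per gene do not show which exons the remaining reads came from.

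**Figure D1:**
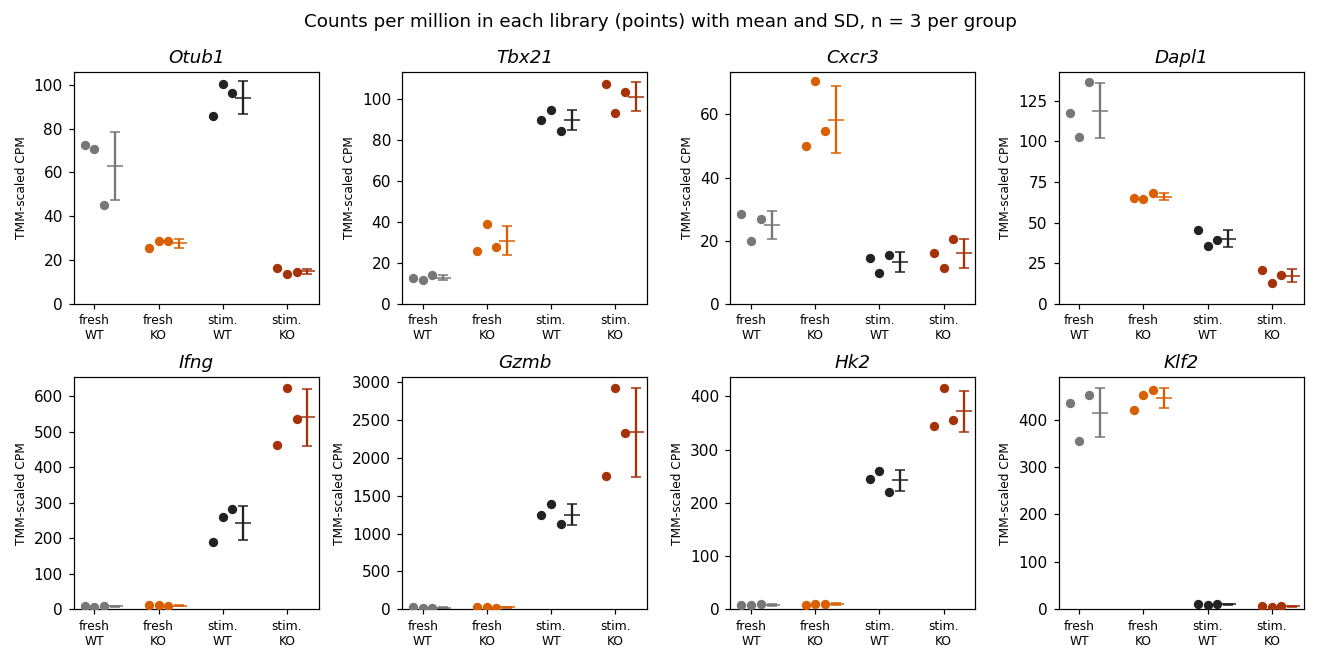
TMM-scaled CPM of named genes (vertical axes, linear from 0) in the 4 groups (horizontal axes); points are libraries, and horizontal marks with error bars are the mean and SD of 3 libraries. Otub1 was at 62.8 and 27.6 CPM in fresh wild type and knockout, and at 94.0 and 14.8 CPM after stimulation.

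The effect of Otub1 loss in resting cells was addressed by comparing fresh knockout with fresh wild type. Of 21 memory-phenotype genes 6 rose in the knockout, and without wild-type replicate 2 there was 1 (camera adjusted p = 2.7e-10 for the list; adjusted p = 0.0527 with an estimated correlation). Tbx21, which encodes T-bet, a transcription factor of effector and memory cells, rose from 12.7 ± 1.20 to 30.7 ± 7.08 CPM (log2 fold change 1.28, SE 0.13, edgeR adjusted p = 0.000301, n = 3 per group). Its target Cxcr3, a chemokine receptor of memory cells, rose from 25.0 ± 4.41 to 58.4 ± 10.8 CPM, and Eomes, the related transcription factor, from 63.2 ± 8.94 to 97.9 ± 18 CPM (edgeR adjusted p = 0.00745 and 0.0192). The chemokine receptor gene Ccr2 rose from 5.37 ± 1.07 to 11.6 ± 0.988 CPM (edgeR adjusted p = 0.00907).

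Across all genes, 125 were higher and 28 lower in fresh knockout, of 12759 tested, and 24 of these differed by at least 2-fold. The groups did not overlap for 20% of genes, against 10% by chance. Among genes that met the limits on level and overlap for naming, the highest fold changes were those of Aqp9, a channel for water and glycerol, from 2.82 ± 0.629 to 13.9 ± 4.23 CPM (log2 fold change 2.32, SE 0.22), and Pak6, a kinase, from 0.974 ± 0.368 to 4.62 ± 0.381 CPM (edgeR adjusted p = 0.000131 and 6.08e-05). Samd3, Pdlim4, Gpr97 and Ctla2a rose too, with log2 fold changes of 1.65, 1.5, 1.40 and 1.19. Dapl1, a gene of naive T cells, fell from 119 ± 16.9 to 66.0 ± 2.00 CPM (log2 fold change −0.85, SE 0.13, edgeR adjusted p = 0.00679). Syt11, a synaptotagmin, fell from 41.2 ± 0.876 to 29.8 ± 1.44 CPM, and the olfactory receptor gene Olfr1033 from 50.7 ± 4.73 to 33.7 ± 3.06 CPM (edgeR adjusted p = 0.0099 and 0.0104). Without wild-type replicate 2 the counts were 21 higher and 8 lower, without wild-type replicate 3 they were 65 and 9, and without knockout replicate 3 they were 74 and 11. Without knockout replicate 1 the number of lower genes was 8 and without knockout replicate 2 it was 76. The share of higher genes among the calls was 81.7%. It was 69.0% of 329 calls with DESeq2 and 58.9% of 90 calls without the libraries with Y-linked reads. Samd3, Cxcr3 and Ccr2 lost the call without wild-type replicate 2 (edgeR adjusted p = 0.0516), as did Pdlim4 and Eomes (edgeR adjusted p = 0.0575 and 0.111).

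Of the 21 memory-phenotype and IL-15-responsive genes, 6 rose in fresh knockout cells: Tbx21, Cxcr3, Eomes, Samd3, Cd44 and Il2rb, the last named after its values were seen. Adjusted over the list alone, 12 rose and 1 fell. Cd44, an adhesion receptor of antigen-experienced cells, went from 56.5 ± 4.06 to 77.6 ± 11.3 CPM, and Il2rb, the IL-2 and IL-15 receptor beta chain, from 281 ± 11.2 to 394 ± 70.4 CPM (edgeR adjusted p = 0.0329 and 0.0288). Cd44 lost the call without wild-type replicate 1 or 2 or knockout replicate 2 or 3, and Il2rb without wild-type replicate 2 or 3, with edgeR adjusted p of up to 0.143 and 0.119. NK cell markers, which share receptors with memory CD8 T cells, had a median log2 fold change of −0.51, and 3 of the 12 libraries had Y-linked reads, 1 in each fresh group.

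Effector molecules were higher in fresh knockout by camera (adjusted p = 1.73e-05; adjusted p = 0.631 with an estimated correlation). Of 23 members, 2 rose over all genes and 8 adjusted over the list alone. Besides Tbx21 this was Ccl4, a chemokine, from 8.16 ± 0.947 to 13.7 ± 1.80 CPM (edgeR adjusted p = 0.0219), which lost the call without wild-type replicate 2 or knockout replicate 1 (edgeR adjusted p of up to 0.126). Ccl5 was at 88.9 ± 12.3 and 116 ± 13.0 CPM and was not called (edgeR adjusted p = 0.0764). Among 21 naive and quiescence genes 2 fell, over all genes and adjusted over the list alone: Dapl1 and Igfbp4, an insulin-like growth factor binding protein, from 199 ± 35.0 to 130 ± 27.4 CPM (edgeR adjusted p = 0.0329). Igfbp4 lost the call without wild-type replicate 2 or 3 or knockout replicate 1 or 3 (edgeR adjusted p of up to 0.177). The naive list as a whole did not pass camera (adjusted p = 0.299), except without knockout replicate 2 (adjusted p = 0.0414).

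Interferon-response genes depended on 1 library. With all libraries, none of the 24 members passed edgeR over all genes or adjusted over the list alone, 14 were higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Estimates were positive for 23, and camera placed the list higher (adjusted p = 2.08e-11; adjusted p = 0.631 with an estimated correlation). Summed CPM of the list was 3757 in wild-type replicate 1, against 2388 and 2450 in the other wild-type libraries and 3590, 3631 and 3488 in the knockout. Without wild-type replicate 1, 18 of the 24 rose. Mx1, an antiviral GTPase, was at 71.2 ± 33.2 CPM in wild type and 109 ± 16.8 CPM in knockout.

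Few signalling genes passed in fresh cells. Among 14 NF-kappaB targets 1 rose, and 2 adjusted over the list alone: Nfkb2, a subunit of the noncanonical pathway, went from 86.1 ± 1.37 to 110 ± 5.98 CPM (edgeR adjusted p = 0.0114; 0.0609 without wild-type replicate 2). The list did not pass camera (adjusted p = 0.137), but did without wild-type replicate 1 or knockout replicate 1 (adjusted p = 0.0426 and 0.0292). Of 23 activation and costimulation genes 1 rose, Cd44, and 2 adjusted over the list alone (camera adjusted p = 0.567). None rose without wild-type replicate 1 or 2 or knockout replicate 2 or 3, and 2 rose without knockout replicate 1. IL-2 and STAT5 targets were higher by camera (adjusted p = 0.0214; adjusted p = 0.631 with an estimated correlation), with 5 of 14 higher adjusted over the list alone. That call was lost without wild-type replicate 2, wild-type replicate 3 or knockout replicate 2 (camera adjusted p = 0.0878, 0.101 and 0.104), and without the libraries with Y-linked reads (0.217).

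The remaining 20 lists, those for interferon and for IL-2 and STAT5 aside, had no member called over all genes in fresh cells. Together with those they held 288 measured members, counted once per list, of which 33 were higher and 20 lower in edgeR at an unadjusted p under 0.05. DESeq2 called 5 higher and 1 lower among them, and limma-voom 1 lower. Adjusted over the list alone, 1 inhibitory receptor was higher, and 1 FOXO target, 1 ATF4 target, 1 CD4 T cell marker, 1 NK cell marker and 1 erythroid marker were lower. Dendritic cell markers were lower by camera (adjusted p = 0.0123; adjusted p = 0.772 with an estimated correlation), a call lost without wild-type replicate 3 or knockout replicate 2 (adjusted p = 0.169 and 0.432), and without the libraries with Y-linked reads the direction turned (adjusted p = 0.825). FOXO targets did not pass (camera adjusted p = 0.152; 0.0166 without knockout replicate 2 and 0.011 without the libraries with Y-linked reads). Neither did lists for CD8 T cell identity, inhibitory receptors, glycolysis, respiratory chain, cholesterol synthesis, ATF4 targets, ribosome biogenesis, S phase, mitosis, immediate early genes, OTUB1 partners and related deubiquitinases, or sex-linked genes. The same held for markers of B cells, CD4 T cells, NK cells, myeloid cells and erythroid cells (camera adjusted p from 0.0734 to 0.957), and the 1 measured platelet marker, Itga2b, was not called. Some of these passed camera with 1 library left out: cholesterol synthesis without wild-type replicate 1 (adjusted p = 0.0189), B cells without knockout replicate 2 (0.0264), NK cells without knockout replicate 1 (0.00372), myeloid cells without wild-type replicate 1 or knockout replicate 3 (0.0212 and 0.000216) and erythroid cells without knockout replicate 3 (0.0412). For sex-linked genes the median log2 fold change was 0.07 and the mean 0.14 while camera pointed lower. Camera also pointed lower for mitosis, ATF4 targets and ribosome biogenesis, against a mean or median above 0 (adjusted p = 0.937, 0.916 and 0.682).

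**Figure D2:**
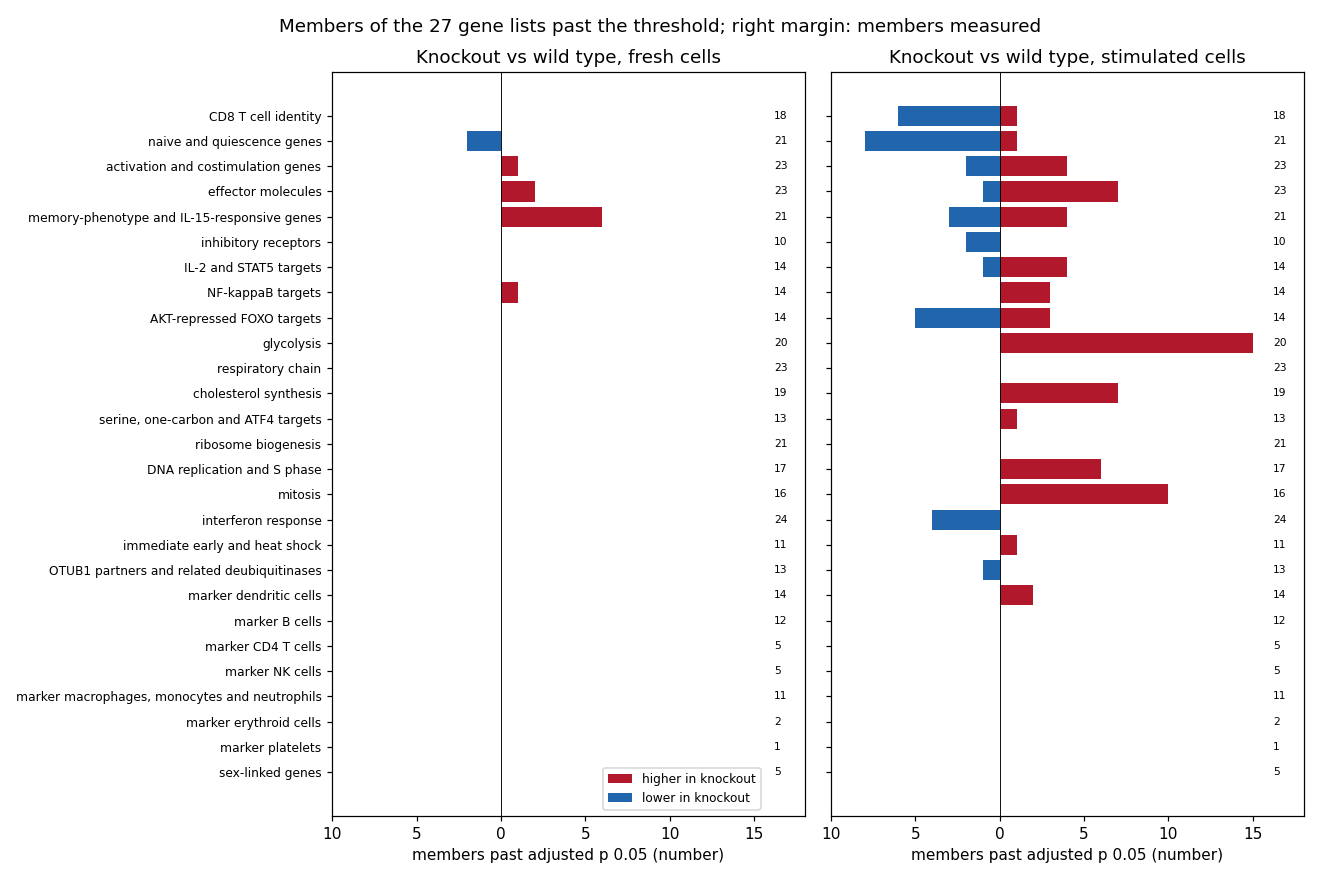
Number of members of each of the 27 gene lists that passed an edgeR adjusted p of 0.05, knockout against wild type, in fresh and in stimulated cells; bars to the right are genes higher in knockout, bars to the left are genes lower, and the number of members measured stands at the right. The longest bars are the 6 memory-phenotype genes in fresh cells and the 15 glycolysis genes in stimulated cells.

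The effect of Otub1 loss on activated cells was addressed by comparing the stimulated groups. Of 23 effector molecules 7 rose in the knockout and 1 fell (camera adjusted p = 5.33e-05; adjusted p = 0.314 with an estimated correlation). Ifng, which encodes interferon gamma, rose from 244 ± 47.9 to 541 ± 80.2 CPM (log2 fold change 1.15, SE 0.12, edgeR adjusted p = 0.000106, n = 3 per group). Gzmb, the cytotoxic protease granzyme B, rose from 1251 ± 134 to 2339 ± 585 CPM, and Serpinb9, an inhibitor of granzyme B, from 216 ± 8.72 to 424 ± 73.3 CPM (edgeR adjusted p = 0.00216 and 8.74e-05). Csf2, the cytokine GM-CSF, rose from 11.0 ± 2.28 to 29.3 ± 7.84 CPM and Il3, interleukin 3, from 4.27 ± 0.870 to 13.7 ± 4.71 CPM (edgeR adjusted p = 0.000461 and 0.00228). Of 20 glycolysis genes 15 rose, and of 16 mitosis genes 10.

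In all, 648 genes were higher and 539 lower in stimulated knockout, 97 of them by at least 2-fold, with a median called change of 1.31-fold. The groups did not overlap for 27.4% of genes, against 10% by chance. Among genes that met the limits on level and overlap for naming, Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, had the highest fold change, from 3.87 ± 0.869 to 15.6 ± 6.87 CPM (log2 fold change 2.01, SE 0.25). Dclk1, a kinase, rose from 3.44 ± 0.564 to 13.1 ± 3.32 CPM and Ier3, an early response gene, from 3.47 ± 0.146 to 13.1 ± 3.09 CPM (edgeR adjusted p = 8.97e-05 and 0.000122). Egln3, a prolyl hydroxylase induced by low oxygen, went from 44.9 ± 22.2 to 139 ± 76.9 CPM, and Bnip3, a mitophagy gene, from 22.3 ± 10.9 to 59.9 ± 29.8 CPM (edgeR adjusted p = 0.00788 and 0.0142). Gpr97, Papss2 and Acvrl1 rose with log2 fold changes of 1.61, 1.49 and 1.41. Of the genes that fell, Npas4, an activity-induced transcription factor, went from 46.4 ± 4.70 to 19.4 ± 4.56 CPM, and Itgae, the CD103 integrin chain, from 18.7 ± 1.83 to 9.43 ± 2.91 CPM (log2 fold change −1.26 and −0.98, edgeR adjusted p = 0.000122 and 0.0027). Dapl1 fell from 40.1 ± 5.23 to 17.3 ± 4.03 CPM, and Scml4 and Camk2b had log2 fold changes of −0.93 and −0.86. Without wild-type replicate 3 the counts were 258 higher and 256 lower, and without wild-type replicate 2 the number of higher genes was 373. Bnip3 lost the call without knockout replicate 2 (edgeR adjusted p = 0.0637), and without the libraries with Y-linked reads 507 genes were higher and 359 lower.

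Of 20 measured glycolysis genes, 15 rose over all genes and 17 adjusted over the list alone. Hk2, the hexokinase of activated cells, rose from 242 ± 20.3 to 372 ± 38.4 CPM (log2 fold change 0.62, SE 0.08), Pfkl from 195 ± 31.7 to 301 ± 23.6 CPM, Pgam1 from 503 ± 56.3 to 700 ± 43.7 CPM and Gapdh from 595 ± 57.2 to 807 ± 39.9 CPM (edgeR adjusted p from 0.000408 to 0.000964). The list was higher by camera (adjusted p = 6.44e-16; adjusted p = 0.296 with an estimated correlation). Summed CPM of the list was 10967, 11600 and 9200 in the wild-type libraries and 13678, 17442 and 13227 in the knockout. Without wild-type replicate 3, the lowest of these, 10 of the 20 rose.

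Cell cycle genes rose in stimulated knockout: 10 of 16 mitosis genes (15 adjusted over the list alone) and 6 of 17 S phase genes (12 adjusted over the list alone). Ccnb1, cyclin B1, rose from 38.1 ± 4.72 to 52.8 ± 2.69 CPM, Rrm1, a subunit of ribonucleotide reductase, from 370 ± 34.0 to 462 ± 7.19 CPM and Rrm2, its partner, from 225 ± 19.8 to 290 ± 22.2 CPM (edgeR adjusted p = 0.00678, 0.00349 and 0.00416). By camera both lists were higher (adjusted p = 9.98e-12 and 5.17e-09; adjusted p = 0.296 for each with an estimated correlation). The member counts moved with single libraries. For mitosis they were 2, 1, 3 and 5 without wild-type replicate 2, wild-type replicate 3, knockout replicate 1 and knockout replicate 3, and for S phase 3 without each of the first 3 of these.

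Of 19 cholesterol synthesis genes, 7 rose, 10 adjusted over the list alone, with Fdps, farnesyl diphosphate synthase, from 122 ± 10.7 to 179 ± 3.77 CPM (edgeR adjusted p = 8.97e-05) and Mvd from 26.5 ± 1.85 to 35.1 ± 3.74 CPM. Camera placed the list higher (adjusted p = 1.28e-09; adjusted p = 0.296 with an estimated correlation), and 3 members rose without wild-type replicate 3. Of the effector molecules 8 were higher and 1 lower adjusted over the list alone. The lower one was Nkg7, named after its values were seen, which did not pass without wild-type replicate 2 or 3 or knockout replicate 1 or 2. IL-2 and STAT5 targets had 4 of 14 higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00108; adjusted p = 0.306 with an estimated correlation). Lif, a cytokine, rose from 121 ± 14 to 216 ± 46.0 CPM and Ltb, lymphotoxin beta, fell from 171 ± 14.7 to 125 ± 15.2 CPM (edgeR adjusted p = 0.00136 and 0.00562). For the IL-2 and STAT5 list 2 rose without any 1 of wild-type replicates 2 and 3 and knockout replicates 2 and 3.

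Members of the lists for CD8 T cell identity and naive cells moved both ways in stimulated knockout. Of 18 CD8 T cell identity genes, 6 fell and 1 rose, 9 and 1 adjusted over the list alone. Cd3d, Cd3g and Cd3e, chains of the T cell receptor complex, went from 207 ± 5.55 to 157 ± 2.92, from 168 ± 5.23 to 120 ± 7.30 and from 174 ± 2.93 to 140 ± 9.57 CPM (edgeR adjusted p = 0.000108, 0.00021 and 0.00118). Thy1 rose from 477 ± 25.5 to 602 ± 47.3 CPM (edgeR adjusted p = 0.00446). The list was lower by camera (adjusted p = 6.02e-06; adjusted p = 0.11 with an estimated correlation). Of 21 naive and quiescence genes 8 fell and 1 rose, 8 and 3 adjusted over the list alone (camera adjusted p = 0.00762; adjusted p = 0.314 with an estimated correlation). Klf2 and S1pr1, which keep resting T cells in circulation, fell from 9.75 ± 1.32 to 5.71 ± 0.433 CPM and from 11.5 ± 1.66 to 6.91 ± 1.11 CPM, and Tcf7, a transcription factor of naive and memory cells, from 283 ± 21.7 to 229 ± 19.7 CPM (edgeR adjusted p = 0.00268, 0.00349 and 0.0105). Summed CPM of the naive list was 3319 ± 14.1 in wild type and 3324 ± 178 in knockout, so the list total did not fall, and that of the identity list was 6016 ± 93.8 and 5499 ± 170. Without wild-type replicate 3, 4 of the naive genes fell.

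Other lists held members that moved both ways, over all genes or adjusted over the list alone. Among 14 FOXO targets 3 rose and 5 fell, 6 and 5 adjusted over the list alone. Their median log2 fold change was 0.07 and their mean −0.03 (camera adjusted p = 0.984, lower). Without wild-type replicate 3 or knockout replicate 2 none of the FOXO targets rose, and without wild-type replicate 2 there was 1. Inhibitory receptors had 2 of 10 lower, and 2 higher and 4 lower adjusted over the list alone. Cd160 fell from 66.0 ± 3.71 to 41.6 ± 2.61 CPM and Pdcd1, which encodes PD-1, from 100 ± 13.9 to 67.7 ± 8.54 CPM (edgeR adjusted p = 8.97e-05 and 0.0157). Pdcd1 lost the call without wild-type replicate 3 or knockout replicate 2 (edgeR adjusted p of up to 0.0919). For this list the median log2 fold change was 0.05 and the mean 0.06, while camera pointed lower (adjusted p = 0.208), and fry passed (adjusted p = 0.0322, lower). Memory-phenotype genes had 4 of 21 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.419). With 1 library left out in turn, 1 to 4 of them rose and up to 2 fell. Itgb1, the beta 1 integrin, rose from 178 ± 4.93 to 224 ± 5.12 CPM (edgeR adjusted p = 0.0012).

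Activation genes had 4 of 23 higher and 2 lower, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0231; adjusted p = 0.486 with an estimated correlation). Il2ra, the IL-2 receptor alpha chain, went from 945 ± 28.5 to 1184 ± 107 CPM and Egr3, an early transcription factor, from 63.9 ± 6.91 to 45.4 ± 5.91 CPM (edgeR adjusted p = 0.0205 and 0.0083). Il2ra lost the call without wild-type replicate 2 or 3 or knockout replicate 2, and Egr3 without wild-type replicate 3 (edgeR adjusted p of up to 0.0926 and 0.0563). The activation list lost its camera call without wild-type replicate 1 or knockout replicate 2 (adjusted p = 0.338 and 0.0706), and with sex as a covariate (0.0501). In edgeR 1 of its members rose without wild-type replicate 2 or 3 or knockout replicate 2. Among NF-kappaB targets 3 of 14 rose, 7 with 1 lower adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.486 with an estimated correlation). Nfkb1, a subunit of the pathway, rose from 909 ± 24.7 to 1100 ± 71.8 CPM (edgeR adjusted p = 0.00564). This list lost its camera call without wild-type replicate 1 or knockout replicate 3 (adjusted p = 0.122 and 0.117), with sex as a covariate (0.0501) and without the libraries with Y-linked reads (0.0719). Without knockout replicate 3, 1 member rose. Y-linked reads were in 1 of the 3 stimulated knockout libraries and 0 of the stimulated wild-type ones.

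Interferon-response genes fell in stimulated knockout, 4 of 24 over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0305; adjusted p = 0.802 with an estimated correlation). Gbp2, a guanylate-binding protein, fell from 900 ± 108 to 653 ± 73.6 CPM (edgeR adjusted p = 0.00922). Ifit3 was lower as well, at 8.72 ± 1.52 and 3.98 ± 0.868 CPM (edgeR adjusted p = 0.0344), and lost the call without any 1 of the 6 stimulated libraries (edgeR adjusted p of up to 0.117). The camera call was lost without wild-type replicate 1, wild-type replicate 2 or knockout replicate 3 (adjusted p = 0.122, 0.0817 and 0.328), with sex as a covariate (0.119) and without the libraries with Y-linked reads (0.313). In edgeR 2 members fell without wild-type replicate 2, knockout replicate 1 or knockout replicate 3.

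Single members passed on other lists. Junb, an AP-1 subunit, rose from 130 ± 15.8 to 180 ± 15.3 CPM, 1 of 11 immediate early genes (edgeR adjusted p = 0.0045; camera adjusted p = 0.14). Slc7a11, a cystine transporter, was the 1 of 13 ATF4 targets that rose (edgeR adjusted p = 0.0442; camera adjusted p = 0.521), and Cyld, a deubiquitinase, the 1 of 13 OTUB1 partners and related deubiquitinases that fell (edgeR adjusted p = 0.0497; camera adjusted p = 0.521). Slc7a11 lost the call without wild-type replicate 2 or 3 or knockout replicate 1 or 2, and Cyld without any 1 stimulated library except knockout replicate 2 (edgeR adjusted p of up to 0.214 and 0.19). Junb and Slc7a11 also passed adjusted over the list alone, and Cyld did not. Of 14 dendritic cell markers 2 rose, over all genes and adjusted over the list alone: Batf3 from 16.7 ± 2.81 to 32.2 ± 6.79 CPM, and Zbtb46 (edgeR adjusted p = 0.00137 and 0.0169). Batf3 is also known in activated T cells. Zbtb46 lost the call without wild-type replicate 2 or 3 or knockout replicate 3 (edgeR adjusted p of up to 0.073). The dendritic cell list had a median log2 fold change of −0.18 and a mean of 0.19 (camera adjusted p = 0.684, higher).

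No member passed edgeR, over all genes or adjusted over the list alone, on 9 lists with 85 measured members. These were respiratory chain, ribosome biogenesis, sex-linked genes and the markers of B, CD4 T, NK, myeloid and erythroid cells and platelets. At an unadjusted p under 0.05 edgeR had 3 higher and 1 lower, and DESeq2 and limma-voom each called 1 higher. Camera adjusted p for the 8 of these lists with more than 1 measured member ran from 0.0985 to 0.984. Ribosome biogenesis genes passed without wild-type replicate 3 or knockout replicate 2 (camera adjusted p = 0.0456 and 0.00261).

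**Figure D3:**
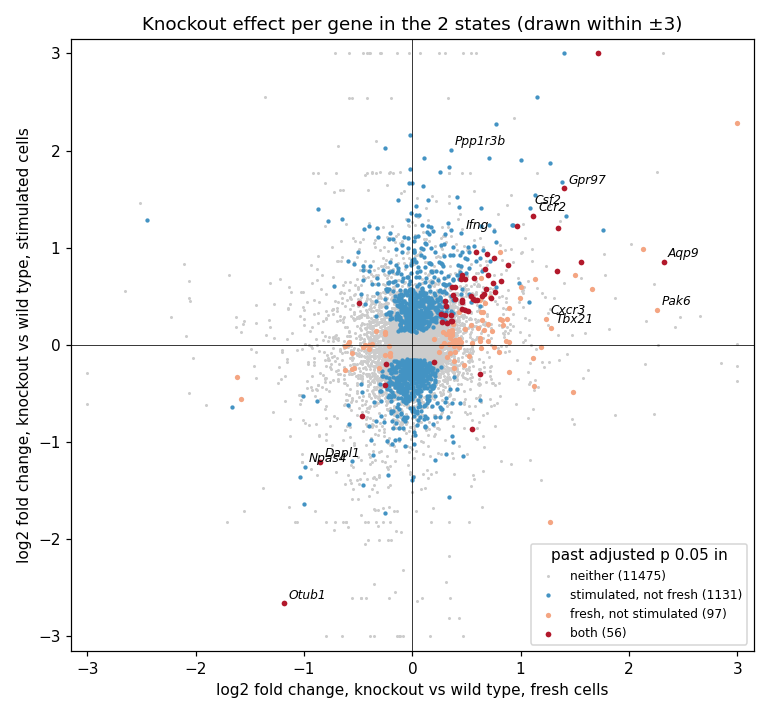
Log2 fold change of knockout against wild type in fresh cells (horizontal axis) and in stimulated cells (vertical axis), 1 point per gene tested, with called genes in colour and 35 genes beyond the axis limits of ±3 drawn at the edge. Of the called genes, 56 were called in both states, 97 in fresh cells and not in stimulated cells, and 1131 in stimulated cells and not in fresh cells.

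Genes called in both states mostly shared their direction. In both states 47 were higher in the knockout, against 6.35 if the lists of calls were independent (Fisher's exact p = 4.61e-29), and 5 were lower, against 1.18 (Fisher's exact p = 0.00579). The lower genes were Otub1, Dapl1, Syt11, Clcn4-2 and Zdhhc20, the last 2 named after their values were seen. Otub1 is the targeted gene, so its place among the 5 was set by the design, and the test was not run without it. In fresh cells Clcn4-2 kept the call only without wild-type replicate 1, and Zdhhc20 only without knockout replicate 1 (edgeR adjusted p of up to 0.157 and 0.152), and in stimulated cells Zdhhc20 kept it only without knockout replicate 2 (up to 0.121). Aqp9, Gpr97, Ccr2, Cd44 and Nfkb2 were among the 47. So were Runx3 and Hopx, regulators of CD8 T cell differentiation named after their values were seen, with log2 fold changes of 0.26 and 0.74 in fresh and 0.32 and 0.64 in stimulated cells. In fresh cells Runx3 lost the call without wild-type replicate 2 or 3 or knockout replicate 2 or 3 (edgeR adjusted p of up to 0.137), and in stimulated cells Nfkb2 without knockout replicate 3 (0.0725) and Cd44 without wild-type replicate 2 or knockout replicate 3 (up to 0.087). Of the 153 genes called in fresh cells, 123 had the same sign in stimulated cells (80.4%). Across all genes the correlation of the fold changes was 0.15 (Pearson; genes are not independent replicates). The comparisons share no library, though both come from 1 fit, so a gene with a small fitted spread can pass more easily in both. Whether fresh and stimulated cells came from the same animals is not known. If they did, differences between animals would enter both comparisons. Fisher's exact test also treats genes as independent, which they are not.

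Stimulation was compared with the fresh state in each genotype, to describe activation itself. In wild type 21 of 23 activation and costimulation genes rose and 2 fell (camera adjusted p = 1.4e-06; adjusted p = 0.153 with an estimated correlation). Il2ra, the IL-2 receptor alpha chain, rose from 4.77 ± 1.26 to 945 ± 28.5 CPM (log2 fold change 7.63, SE 0.12, edgeR adjusted p = 2.3e-16, n = 3 per group). The chemokine genes Xcl1 and Ccl3 rose from 4.43 ± 1.32 to 817 ± 157 CPM and from 3.99 ± 0.862 to 691 ± 164 CPM. Klf2 fell from 415 ± 51.6 to 9.75 ± 1.32 CPM and S1pr1 from 534 ± 36.6 to 11.5 ± 1.66 CPM (edgeR adjusted p = 1.09e-15 and 1.39e-15). Fresh cells, labelled untreated, were taken as not cultured, so these differences include the effect of 24 h in culture.

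In wild type 5207 genes rose and 5288 fell, and in knockout 5323 rose and 5386 fell. The balance moved with the scaling: with upper-quartile factors 4663 rose and 5867 fell in wild type, and 4801 and 5909 in knockout. The groups did not overlap for 84.1% and 84.6% of genes, against 10% by chance. Among genes called in both genotypes 9901 had the same sign and 8 the opposite one, with a correlation of 0.96 across genes, which are not independent replicates. Il3 had 0 counts in both fresh groups and was at least 74.3-fold higher after stimulation in wild type and at least 283-fold higher in knockout, against the floor of 3 counts over the group. Cth and Asns, enzymes that make cysteine and asparagine, rose in wild type from 0.311 ± 0.0994 to 139 ± 20 CPM and from 1.04 ± 0.490 to 244 ± 16.8 CPM. Fos, an immediate early gene, fell from 987 ± 212 to 10.4 ± 1.10 CPM, Ggt1, an enzyme of glutathione breakdown, from 103 ± 5.23 to 0.97 ± 0.0598 CPM and Cd7, a receptor of resting T cells, from 201 ± 12.0 to 2.30 ± 0.564 CPM (edgeR adjusted p = 6.27e-13, 4.58e-16 and 1.67e-16). The list that holds Fos was chosen for handling and dissociation stress. Such stress in the fresh cells was not told apart from an effect of stimulation. The Y-linked gene Kdm5d also passed in wild type (edgeR adjusted p = 0.0423). Its reads came from fresh replicate 3, without which it did not pass (edgeR adjusted p = 0.93), and it also lost the call without any 1 stimulated wild-type library.

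Growth and division lists rose almost whole in wild type. All 13 ATF4 targets, 21 ribosome biogenesis genes and 17 S phase genes rose, as did 15 of 16 mitosis genes, 22 of 23 respiratory chain genes, 18 of 19 cholesterol synthesis genes and 17 of 20 glycolysis genes, of which 1 fell. Psat1, an enzyme of serine synthesis, rose from 40.0 ± 1.06 to 634 ± 18.4 CPM, Mcm5, a replication helicase subunit, from 93.3 ± 7.87 to 573 ± 15.1 CPM, Hk2 from 7.71 ± 1.23 to 242 ± 20.3 CPM and Cycs, cytochrome c, from 76.4 ± 2.12 to 294 ± 7.95 CPM (edgeR adjusted p = 1.8e-17, 5.99e-15, 4.08e-15 and 8.43e-15). Camera adjusted p was 1.4e-06 for ATF4 targets, 6.28e-10 for ribosome biogenesis, 1.69e-08 for S phase, 1.7e-05 for mitosis, 1.17e-05 for the respiratory chain, 8.19e-06 for cholesterol synthesis and 5.66e-05 for glycolysis. In that order, the adjusted p with an estimated correlation was 0.153, 0.153, 0.247, 0.366, 0.247, 0.326 and 0.384.

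Of 23 effector molecules 15 rose and 7 fell, of 14 IL-2 and STAT5 targets 12 rose and 2 fell, and of 14 NF-kappaB targets 10 rose and 2 fell (camera adjusted p = 0.046, 0.00155 and 0.0206; adjusted p = 0.481, 0.256 and 0.366 with an estimated correlation). The effector call was lost without fresh wild-type replicate 2 and with the filter of CPM above 1 (camera adjusted p = 0.0586 and 0.0549). Of 18 CD8 T cell identity genes 14 fell and 3 rose, of 21 naive genes 16 fell and 4 rose, of 14 FOXO targets 12 fell and 2 rose, and of 24 interferon-response genes 20 fell and 4 rose (camera adjusted p = 0.00066, 5.58e-05, 0.000137 and 0.00155; adjusted p = 0.153, 0.153, 0.247 and 0.503 with an estimated correlation). Cd8b1 fell from 1198 ± 72.8 to 226 ± 21.6 CPM and Irf7, an interferon-induced factor, from 256 ± 82.6 to 14.9 ± 3.10 CPM, while Gbp2 rose from 116 ± 16.3 to 900 ± 108 CPM (edgeR adjusted p = 1.4e-12, 5.58e-11 and 6.59e-13). Lists that did not pass camera were inhibitory receptors with 5 of 10 higher and 4 lower, immediate early genes with 2 of 11 higher and 7 lower, memory-phenotype genes with 9 of 21 higher and 11 lower, and OTUB1 partners and related deubiquitinases with 6 of 13 higher and 6 lower (adjusted p = 0.839, 0.0858, 0.839 and 0.954). By fry inhibitory receptors (adjusted p = 0.000594, higher) and immediate early genes (5.98e-06, lower) passed. For memory-phenotype genes the median log2 fold change was −0.69 and the mean 0.10, and for OTUB1 partners and related deubiquitinases they were 0.09 and −0.09.

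Markers of other spleen cells fell with stimulation in wild type: 12 of 14 dendritic cell markers, with 1 higher, all 12 B cell markers, all 11 myeloid markers, all 5 NK cell markers, 3 of 5 CD4 T cell markers, with 1 higher, both erythroid markers and the 1 platelet marker. Camera adjusted p was 0.00066 for dendritic cells, 0.000186 for B cells and 0.003 for myeloid cells (adjusted p = 0.366, 0.326 and 0.366 with an estimated correlation). For NK cells, CD4 T cells and erythroid cells it was 0.0516, 0.324 and 0.334, and NK cell markers passed without fresh replicate 1 or 3 (camera adjusted p = 0.0469 and 0.0484), with sex as a covariate (0.049) and without the libraries with Y-linked reads (0.0437). H2-Aa, an MHC class II chain, fell from 291 ± 32.8 to 12.4 ± 1.03 CPM and Cd74, the invariant chain, from 660 ± 60.3 to 57.9 ± 7.41 CPM (edgeR adjusted p = 6.89e-13 and 1.21e-12). Sex-linked genes had 3 of 5 lower over all genes and none adjusted over the list alone, where Y-linked reads were in 1 of the 3 fresh wild-type libraries. Adjusted over the list alone, the counts of the other lists were the same as over all genes.

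In the knockout the numbers of higher and of lower members each differed from wild type by at most 1 gene on all lists but CD8 T cell identity and sex-linked genes. Of CD8 T cell identity genes 14 fell and 0 rose in edgeR, where 3 rose in wild type. None was higher at an unadjusted p under 0.05 or in DESeq2 or limma-voom. Sex-linked genes had 0 called in the knockout by edgeR, DESeq2 or limma-voom, and 0 at an unadjusted p under 0.05. Effector molecules did not pass camera in the knockout (adjusted p = 0.0543), with 14 higher and 6 lower. Cholesterol synthesis genes rose in 19 of 19 and mitosis genes in 16 of 16. Klf2 was at 446 ± 21.4 CPM in fresh and 5.71 ± 0.433 CPM in stimulated knockout, and Il2ra at 4.08 ± 0.359 and 1184 ± 107 CPM (log2 fold change −6.28 and 8.18, edgeR adjusted p = 3.77e-16 and 9.58e-17).

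The interaction asked whether the genotype effect differed between the states. It was more positive in stimulated cells for 89 genes and more negative for 199. Jag2, a Notch ligand, was at 6.39 ± 1.12 and 4.07 ± 0.691 CPM in fresh wild type and knockout and at 4.25 ± 0.925 and 10.5 ± 3.76 CPM after stimulation (log2 difference of the effects 1.95, SE 0.33, edgeR adjusted p = 0.00886). Pak6 was 4.62 ± 0.381 CPM in fresh knockout against 0.974 ± 0.368 CPM, and 17.1 ± 0.535 against 13.3 ± 1.66 CPM after stimulation (log2 difference −1.90, SE 0.24, edgeR adjusted p = 0.00329). Cd3d, Cd3e and Cd3g, named after their values were seen, had more negative effects in stimulated cells (log2 difference −0.35, −0.27 and −0.40, edgeR adjusted p = 0.0102, 0.0484 and 0.0198). Cd3g lost the call without fresh wild-type replicate 2 or stimulated wild-type replicate 3, and Cd3e without any 1 library except stimulated knockout replicate 1 (edgeR adjusted p of up to 0.0528 and 0.129). Without fresh wild-type replicate 2 the counts were 32 and 103, without fresh wild-type replicate 3 they were 43 and 118, and without fresh knockout replicate 1 they were 39 and 127. Without stimulated wild-type replicate 3 they were 32 and 99. Without fresh knockout replicate 3 the higher count was 55 and without stimulated wild-type replicate 1 it was 153. The more positive share of the calls was 30.9%. It was 34.2% of 553 calls with DESeq2 and 45.1% of 122 calls without the libraries with Y-linked reads.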

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

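All tests of explanations in this part were chosen only after the result was seen, except the counts of other splits of the libraries, and so was the fit without the libraries with Y-linked reads.

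The effect of genotype differed between fresh and stimulated cells, by the interaction test, for 89 genes with a more positive effect in stimulated cells and 199 with a more negative one. The lean to negative effects was smaller without the libraries with Y-linked reads, where 45.1% of 122 calls were more positive, against 30.9%. The differences of the log2 fold changes were 1.95 for Jag2, 1.66 for Irs2, 1.65 for Ppp1r3b, 1.63 for Fam46a and 1.53 for Plaur. They were −1.90 for Pak6, −1.61 for Ifit3, −1.47 for Otub1, −1.46 for Aqp9 and −1.42 for Baiap3. The calls of Irs2, Ppp1r3b, Ifit3 and Aqp9 were each lost with some single libraries left out, with edgeR adjusted p of up to 0.0731, 0.0773, 0.0875 and 0.0715. For Irs2 these were fresh wild-type replicates 2 and 3, fresh knockout replicate 1, stimulated wild-type replicate 3 and stimulated knockout replicate 2, and for Aqp9 fresh wild-type replicate 2 and stimulated wild-type replicate 3. For Ppp1r3b they were fresh wild-type replicates 2 and 3, fresh knockout replicates 1 and 3 and stimulated wild-type replicate 3. For Ifit3 the call stayed without fresh wild-type replicate 1, fresh knockout replicate 3 or stimulated knockout replicate 2.

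Gene lists differed in the same test. Camera placed glycolysis (adjusted p = 4.91e-10), cholesterol synthesis (4.91e-10), mitosis (6.6e-07) and S phase (0.00615) higher, and interferon response (3.24e-07), CD8 T cell identity (6.6e-07) and memory-phenotype genes (0.00139) lower, in the knockout effect of stimulated cells relative to fresh cells. With an estimated correlation none of these passed, with adjusted p = 0.581, 0.431, 0.671, 0.68, 0.671, 0.0686 and 0.431 in that order. Called members over all genes were 3, 1 and 1 higher for glycolysis, cholesterol synthesis and mitosis, and 3 lower for each of the lower lists. By fry only CD8 T cell identity of these lists passed. With 1 library left out, other lists passed camera as well: activation genes without fresh wild-type replicate 2, fresh knockout replicate 2 or 3, stimulated wild-type replicate 2 or 3 or stimulated knockout replicate 1 (adjusted p from 0.00361 to 0.0328), and without the libraries with Y-linked reads (0.0348). Ribosome biogenesis passed without fresh wild-type replicate 1, fresh knockout replicate 2 or 3 or stimulated knockout replicate 2 (0.00348 to 0.0475), and naive genes without fresh knockout replicate 3, stimulated wild-type replicate 2 or stimulated knockout replicate 2 (0.0208 to 0.0455). Without fresh knockout replicate 2 the lists of OTUB1 partners and related deubiquitinases (0.0429) and of B cell markers (0.0201) passed, and without fresh knockout replicate 3 those of immediate early genes (0.0382) and dendritic cell markers (0.0328). S phase had 0 called in edgeR over all genes, 6 higher at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 2 higher in DESeq2 and 0 called in limma-voom.

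Other groupings of the same libraries were counted for each comparison. For fresh knockout against wild type the real grouping gave 153 genes and the highest of the other splits 4. For stimulated cells these were 1187 and 1, for stimulation in wild type 10495 and 0, and for stimulation in knockout 10709 and 0. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each case 1 split, the real one, gave as many genes. Every other split of these comparisons puts libraries of both real groups on each side. A real difference between the groups then becomes spread within each side, which lowers the number of calls. The low counts of the other splits therefore do not measure what chance alone would give, and no conclusion is drawn from them. For the interaction 100 of 200 possible splits were drawn and 1 of them, the real one, gave as many as 288 genes. Splits that mix the stimulated libraries also remove the genotype effect there, so they do not bear on the interaction alone, and they gave 5 genes at the most. Only 20 of the possible splits keep the stimulated libraries divided by genotype, too few for a share under 0.05. Of these 8 were drawn, the real one included, and the others gave 77 to 198 genes. Apart from the real one, such splits mix the fresh libraries or swap the genotypes of 1 state. They do not compare the genotype effects of the states either, so these counts do not test the interaction.

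Higher memory-phenotype genes in fresh knockout cells were weighed against sex, other cells and composition. The 6 called members had a median log2 fold change of 0.93, and of 0.83 without the libraries with Y-linked reads. There 6 were positive and 3 still called with fewer libraries, which argues against sex as the whole cause. The members were chosen by their calls with all libraries, which favours positive estimates in this fit as well. The 5 measured NK cell markers had a median log2 fold change of −0.51 with an SD of 0.60, below the median of the called members by more than that SD, which argues against NK cells as the source. A larger share of memory-phenotype cells stays open, since 3 measured members had a negative estimate but these libraries give no levels for naive cells alone. It cannot be told apart from a change of expression within cells, which may give the same counts.

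Higher glycolysis genes in stimulated knockout cells were weighed against sex, a single library and oxygen supply. The 15 called members had a median log2 fold change of 0.48, which was 0.55 without the libraries with Y-linked reads, against sex as the whole cause. Leaving out 1 stimulated library gave at least 0.40, without stimulated wild-type replicate 3, where 10 of the 15 were still called, against a single library as the whole cause. These members too were chosen by their calls with all libraries, which favours positive estimates in these fits. A set of 21 targets of HIF-1 outside glycolysis, chosen after the data were seen, had a median log2 fold change of 0.52. Of these 16 rose, 18 adjusted over the list alone. The standard error of the mean, 0.13, was taken over genes, which are not independent replicates. It does not measure the spread between libraries, and the set was not examined with single libraries left out. Less oxygen in the knockout cultures stays open, since oxygen was not measured and a rise of these targets can have other causes. A direct effect of genotype on these genes was not separated from it.

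Otub1 reads remained in the knockout libraries, at 43.9% of wild type in fresh and 15.8% in stimulated cells. Markers of dendritic, B and myeloid cells, 37 in all, had a median log2 fold change of −3.60 from fresh to stimulated knockout, while Otub1 had −0.89 (SE 0.15). If these markers follow the number of such cells, this argues against them as the source of the reads in stimulated libraries. That number was not measured, and markers may also change within cells in culture. In fresh libraries other cells may contribute, as their own Otub1 level was not measured. Reads from parts of the gene outside the deletion also stay open, since counts per gene do not show exons.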

How the results depend on the processing

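Sex as a covariate and the fit without the libraries with Y-linked reads were chosen only after the data were seen. No paired analysis was possible because the labels number the samples in 1 running series, so the groups compared share no replicate numbers.

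Against the 1.5-fold threshold, edgeR called 5 genes higher and 0 lower in fresh knockout, 9 and 3 in stimulated knockout, 3152 and 3287 with stimulation in wild type, 3310 and 3495 with stimulation in knockout, and 0 and 0 for the interaction, since this test asks for more than a difference from 0. At an unadjusted p under 0.05 that test had 79 higher and 45 lower in fresh knockout, and 110 and 114 for the interaction; DESeq2 and limma-voom were not run against this threshold. With no filter on low counts 202 genes were higher and 43 lower in fresh knockout, and 151 had a more positive interaction. DESeq2 called 227 higher and 102 lower in fresh knockout, and 189 and 364 for the interaction. With limma-voom 49 genes were lower in fresh knockout, with sex as a covariate 57, and with only the groups compared 358 were lower in stimulated knockout. Without the libraries with Y-linked reads 53 genes were higher in fresh knockout, 359 lower in stimulated knockout, and 55 and 67 differed in the interaction. That fit has fewer libraries, and for the others the cause was not tested. The fit of only the groups compared does not apply to the interaction.

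With each library left out in turn, the genes higher and lower ran from 21 to 170 and from 8 to 76 in fresh knockout, from 258 to 796 and from 256 to 511 in stimulated knockout, from 5065 to 5163 and from 5102 to 5205 with stimulation in wild type, from 5195 to 5294 and from 5254 to 5360 with stimulation in knockout, and from 32 to 153 and from 99 to 252 for the interaction. The share of higher genes in fresh knockout was 81.7%, and it was 69.0% with DESeq2, 53.1% without fresh knockout replicate 2 and 58.9% without the libraries with Y-linked reads. For the interaction it was 30.9%, and 43.8% without stimulated wild-type replicate 1 and 45.1% without the libraries with Y-linked reads. Upper-quartile factors moved the median log2 fold change of all genes with stimulation to −0.15 in wild type and −0.14 in knockout, from −0.03 and −0.02, and changed no call of a named gene.

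Direction was followed for results past the threshold. The dendritic cell marker list in fresh cells reversed without the libraries with Y-linked reads (camera adjusted p = 0.825), and the cause was not tested. No named gene reversed in the alternatives run. Apart from single libraries left out, 1904 values of named genes kept their side of the threshold, 183 lost the call and 17 gained it, and for gene lists these were 652, 61 and 10. With single libraries left out they were 1167, 178 and 5 for genes, and 736, 13 and 31 for lists. The 1.5-fold threshold changed 122 of 212 calls of named genes, the fit without the libraries with Y-linked reads 27 of 211, limma-voom 14 of 212 and DESeq2 5 of 211. Of the named genes called in fresh knockout 11 of 31 kept the call with every library left out in turn, in stimulated knockout 63 of 90, with stimulation in wild type 65 of 66 and for the interaction 7 of 13. Depth limits genes near the filter on low counts, where a few reads set the fold change.

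Fry, in place of camera, did not pass effector molecules, interferon response and IL-2 and STAT5 targets in fresh knockout (adjusted p = 0.406 for each) or dendritic cell markers (0.553). In stimulated knockout it did not pass activation genes, NF-kappaB targets and interferon response (0.145, 0.0758 and 0.639). For the interaction it did not pass S phase, cholesterol synthesis, glycolysis, interferon response, memory-phenotype genes and mitosis (0.428, 0.112, 0.287, 0.381, 0.112 and 0.324). It passed inhibitory receptors in stimulated knockout (0.0322). With stimulation in wild type it passed inhibitory receptors, immediate early genes and markers of CD4 T, NK and erythroid cells (0.000594, 5.98e-06, 7.7e-05, 1.03e-05 and 0.00064). Fry asks another question than camera, which compares a list with other genes.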

Other observations

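The gene families and the integrin, receptor and cytokine genes described in this part were chosen only after the data were seen, while the test of the genome near Otub1 was set before its result was seen.

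Receptors that guide T cell traffic changed in both directions in stimulated knockout cells. Of 44 measured integrin and trafficking receptor genes, 6 rose and 7 fell (edgeR). Ccr4, a chemokine receptor for skin homing, rose from 25.0 ± 4.98 to 48.5 ± 5.58 CPM (log2 fold change 0.96, SE 0.13, edgeR adjusted p = 0.000411, n = 3 per group), and Itga5, the fibronectin receptor chain, had a log2 fold change of 0.72 (edgeR adjusted p = 0.000397). The gut-homing integrin chain Itgb7 fell from 134 ± 3.16 to 89.7 ± 9.18 CPM (log2 fold change −0.57, SE 0.06, edgeR adjusted p = 0.000108), as did Itgae, its partner chain (edgeR adjusted p = 0.0027). In fresh cells 4 of the 44 rose, Ccr2, Cxcr3 and Itga5 among them. Ccr2 and Cxcr3 lost that call without wild-type replicate 2, and Itga5 without any 1 fresh library except knockout replicate 1 (edgeR adjusted p of up to 0.137).

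Among 40 measured cytokine and chemokine genes 8 rose and 3 fell in stimulated knockout cells. Tnfsf11, which encodes RANKL, rose from 52.3 ± 6.74 to 81.2 ± 17.0 CPM (log2 fold change 0.64, SE 0.13, edgeR adjusted p = 0.00733, n = 3 per group). Tnfsf14, which encodes LIGHT, was higher in fresh knockout (log2 fold change 0.62, edgeR adjusted p = 0.0244) and lower in stimulated knockout (log2 fold change −0.30, edgeR adjusted p = 0.0366). The call was lost in fresh cells without wild-type replicate 2 or 3 or knockout replicate 2 or 3 (edgeR adjusted p of up to 0.111), and in stimulated cells without wild-type replicate 2 or 3 or knockout replicate 1 or 2 (up to 0.212).

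Genome carried along with the targeted Otub1 allele was tested as a hypothesis for the genes called in the same direction in both states. Otub1 aside, 51 such genes had a position, and 1 of them (1.96%) lay on chromosome 19 within 10 Mb of Otub1, against 229 of 12707 tested genes (1.80%; two-sided Fisher's exact p = 0.605). The others lay outside that window, which argues against flanking genome as the cause for the group.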
